A study of Homo sapiens with 4 samples.

How the data were processed

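RNA-seq was done on 4 samples of the A549 line: 2 with a non-targeting guide (control) and 2 with a guide against UHRF1 (UHRF1 KO). Per the labels' protocols, guides were delivered with the lentiCRISPRv2-hygro lentivirus, cells were selected with hygromycin, RNA was extracted with Trizol, and libraries were made with a SMARTER mRNA-Seq kit. Whether the cells were pools or single clones, and the time after infection, are not given in the sources used here. The submitters' processing notes name FastQC 0.10.1 and the genome build GRCh38; the aligner, the counting tool, the annotation, the use of strand and the handling of reads that match several places are not given in the sources used here.

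The deposited table holds whole-number read counts per gene, not normalized, for 58735 Ensembl gene identifiers, of which 24721 were 0 in all 4 libraries. All 58735 identifiers were found in GENCODE release 29 (GRCh38), which gave symbols, gene types and coordinates. Columns were matched to samples by name. For the controls, the short name with number 1 stands in the description of both samples, so the 2 columns were matched by the replicate number in the sample titles; the group of each column is certain, but which control is number 1 is less so, and this bears only on the replicate block and on the names of left-out controls. Totals ran from 18604598 to 23977168 counts, so 1 count is worth 0.0538, 0.052, 0.0499 and 0.0417 CPM in control 1, control 2, UHRF1 KO 1 and UHRF1 KO 2. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

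Replicates were compared before use. A chi-square test over genes gave 2.65 per degree of freedom for the control pair (15331 genes) and 1.85 for the UHRF1 KO pair (17705 genes), with at least 20 counts per gene, so the libraries of each pair differed by more than counting noise and were kept as 2 replicates.

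Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the group (17030 genes), libraries were scaled by TMM, and the quasi-likelihood test (glmQLFit with robust moderation, glmQLFTest, two-sided) was adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05 and no minimum fold. The biological coefficient of variation was 3.16% and 2 residual degrees of freedom per gene were moderated across genes. Fold changes come from the fit. Each SE is approximate, taken as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. For a gene at 0 in both controls the fold is a lower bound, from the UHRF1 KO level over a floor of 3 counts across the 2 control libraries.

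The 21 gene lists were written from general knowledge before the data were examined; 1 list and some single genes are not reported here, and the other lists were DNA methylation machinery, germline and cancer-testis genes, genes often promoter-methylated in lung cancer, imprinted genes, interferon-stimulated genes, MHC class I antigen presentation, NF-kB targets, G1/S, G2/M, NRF2 targets, MAPK output, epithelial, mesenchymal, lung and gut lineage, ER stress and ATF4 targets, cholesterol synthesis, hypoxia and glycolysis, markers of other cell types, mitochondrially encoded genes and cytosolic ribosomal proteins. Markers of other cell types, mitochondrially encoded genes and cytosolic ribosomal proteins were included as checks of sample makeup and RNA. Lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. The genes named were UHRF1, the 6 largest rises and 6 largest falls among called genes with groups that do not overlap and at least 5 CPM in the higher group (rows without a gene symbol left out), up to 2 called members of each list with the smallest adjusted p, and DNMT1, DNMT3A, DNMT3B, UHRF2, CD274 and CDKN1A. This gave 57 genes.

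The steps were tested on simulated data drawn from the means, sizes and dispersion of the real libraries, with 16573 genes in the step. At a true fold of 1.2, 17 of 49 changed genes were called, at 1.5-fold 35 of 48, at 2-fold 42 of 50 and at 4-fold 49 of 49. Of the calls 4.67% were false, the raised list was called and 0 other lists were. The simulation changed far fewer genes than were called in the real data, which makes the adjusted threshold stricter. It gave all genes the common dispersion and let them vary independently, so it cannot test false list calls under correlation. These rates may not hold for the real comparison.

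Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile factors, no filter, a minimum of 1 CPM in 2 libraries, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, a minimum of 2-fold, and camera with an estimated correlation or fry for the lists. Thinning to equal depth, removal of GC content and length trends with and without recentring of libraries, the 2-fold counts as results of their own, the 8-fold counts with genes at 0 in control set to their bound, the DNA methylation list without UHRF1, and family, gene type and chromosome tests limited to genes with 10 or more counts in both controls were added after seeing the data. GC content and length were known for 99.9% of the tested genes. No column of the table was left out.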

Results

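The transcriptome of A549, an established human lung adenocarcinoma line, was compared between cells given a CRISPR guide against UHRF1 and cells given a non-targeting guide. UHRF1 is the protein that binds hemimethylated DNA and recruits the maintenance methyltransferase DNMT1 at replication. RNA-seq read counts per gene were available for 4 libraries, 2 control and 2 UHRF1 KO. Total counts were 18604598 and 19222886 in the control libraries and 20020366 and 23977168 in the UHRF1 KO libraries. At least 1 count was found for 24600 and 24504 genes in the control libraries and for 28486 and 29341 genes in the UHRF1 KO libraries. Levels are CPM after TMM scaling, given as mean ± SD with n = 2 per group, and log2 fold changes are UHRF1 KO against control with an approximate standard error (SE). Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

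UHRF1 itself (ENSG00000276043, GRCh38 chromosome 19, positions 4903080 to 4962154, plus strand) was lower in both UHRF1 KO libraries. Its level was 98.2 ± 0.90 CPM in control and 39.7 ± 0.79 CPM in UHRF1 KO (SD, n = 2), from 1740 and 1834 counts against 811 and 1000. The log2 fold change was -1.31 (SE 0.055), which is 2.47-fold lower (edgeR adjusted p = 3.92e-20). A guide acts on the DNA and need not remove the transcript, so this level does not measure the protein. It checks the library labels only in part, since 432 called genes were at least 2-fold lower in the same comparison.

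The comparison as a whole asked which genes change when UHRF1 is targeted. Of 17030 genes tested with edgeR, 5445 were higher and 5118 were lower in UHRF1 KO. The large changes were mostly rises, since 2616 of the called genes were at least 2-fold higher and 432 at least 2-fold lower. Among 13715 protein-coding genes tested these counts were 1820 and 294, and among genes reaching 5 CPM in the higher group they were 913 and 194. With libraries recentred as described below, the 2-fold counts were 1962 and 1259. With genes at 0 in both controls set to their lower bound, 797 genes were at least 8-fold higher and 13 lower, and 673 and 20 with recentring. The fitted 8-fold counts of 827 and 13 became 1510 and 42 with no filter and 1062 and 22 with DESeq2, and the falls numbered 40 without UHRF1 KO replicate 1 and 32 without UHRF1 KO replicate 2. The split of all calls rests on the scaling: with GC content and length trends removed and every library recentred on its mean, a choice made after seeing the data, 3543 genes were higher and 8220 lower. That setting shifted the median gene by -0.28 on the log2 scale. Removing the same trends without recentring gave 5947 higher and 4656 lower genes. The share of higher genes among the calls was 51.5% without either step, 56.1% with trends removed and 30.1% with recentring added.

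The 6 rises ranked highest by fitted fold change among genes reaching 5 CPM were all of genes with 0 counts in both control libraries, where that rank depends on the fit. Folds for such genes are given as lower bounds, set against a floor of 3 counts over the 2 control libraries together, and by these bounds 4 of the 6 lie below the 465.7-fold of COL6A3, which had 4 and 2 control counts. PNMA5 (chromosome X, 152988824 to 152994127) reached 112.6 ± 1.71 CPM, at least 1367-fold higher, and MAGEA4 (chromosome X, 151912509 to 151925170) reached 101.7 ± 1.25 CPM, at least 1233-fold higher. The cancer-testis antigens MAGEC2 and CTAG2 were at least 347-fold and at least 312-fold higher. GTSF1, a partner of the piRNA pathway, and the testis serine protease gene PRSS21 were at least 290-fold and at least 285-fold higher. All 6 genes had 475 or more counts in each UHRF1 KO library.

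Among called genes reaching 5 CPM, the 6 largest falls included the signal recognition particle RNA copies RN7SL2, at a log2 fold change of -3.50 (SE 0.52), and RN7SL3, at -2.91 (SE 0.28). RN7SL3 had 215 and 196 counts in control but 14 and 55 in UHRF1 KO, and its value was -4.06 without UHRF1 KO replicate 2, where that of RN7SL2 was -4.50. RN7SL2 had 3704 and 3176 counts in control but 174 and 596 in UHRF1 KO, and its edgeR adjusted p of 0.0266 became 0.0689 with no filter on low counts. It became 0.212 without control replicate 1, 0.194 without control replicate 2 and 0.139 with the replicate number as a block, and was at most 0.0270 in the other 10 alternative fits. The mitochondrial valine tRNA MT-TV fell from 10.3 ± 0.64 to 0.99 ± 0.25 CPM, a log2 fold change of -3.34 that was -2.73 with GC content and length trends removed. ANKRD1, a target of YAP signalling (chromosome 10, 90912096 to 90921276), fell 8.11-fold, from 5.02 ± 0.36 to 0.62 ± 0.079 CPM. KLHDC7A fell 6.03-fold and SYT6, a synaptotagmin, fell 5.68-fold. The RN7SL copies are near-identical to one another, and how reads that match several places were counted is not given in the sources used here. RN7SL2, RN7SL3 and MT-TV are not mRNAs, while the libraries were made with an mRNA kit. Their counts therefore need not follow their levels in the cells, and this was not tested.

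Gene groups were compared through 21 lists fixed before the data were examined, as were the main test and the rule for the genes named. Members of a list that are named beyond the rule were chosen after their values were seen. Under camera with its preset correlation, 7 lists were higher and 7 lower. With a correlation estimated from the 4 libraries, camera called 0 lists at an adjusted p under 0.05, with 4 higher and 1 lower at an unadjusted p under 0.05. The smallest adjusted p was then 0.110, and fry, which asks only whether a list moves one way, called 13 lists higher and 7 lower. The median log2 fold change over all genes tested was 0.02. Some families that share a symbol prefix also had low medians, such as -0.46 (MRPL), -0.44 (NDUFA) and -0.38 (TIMM), while others rose, such as IL at 1.30. Falls of moderate size were therefore not particular to the lists.

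**Figure D1:**
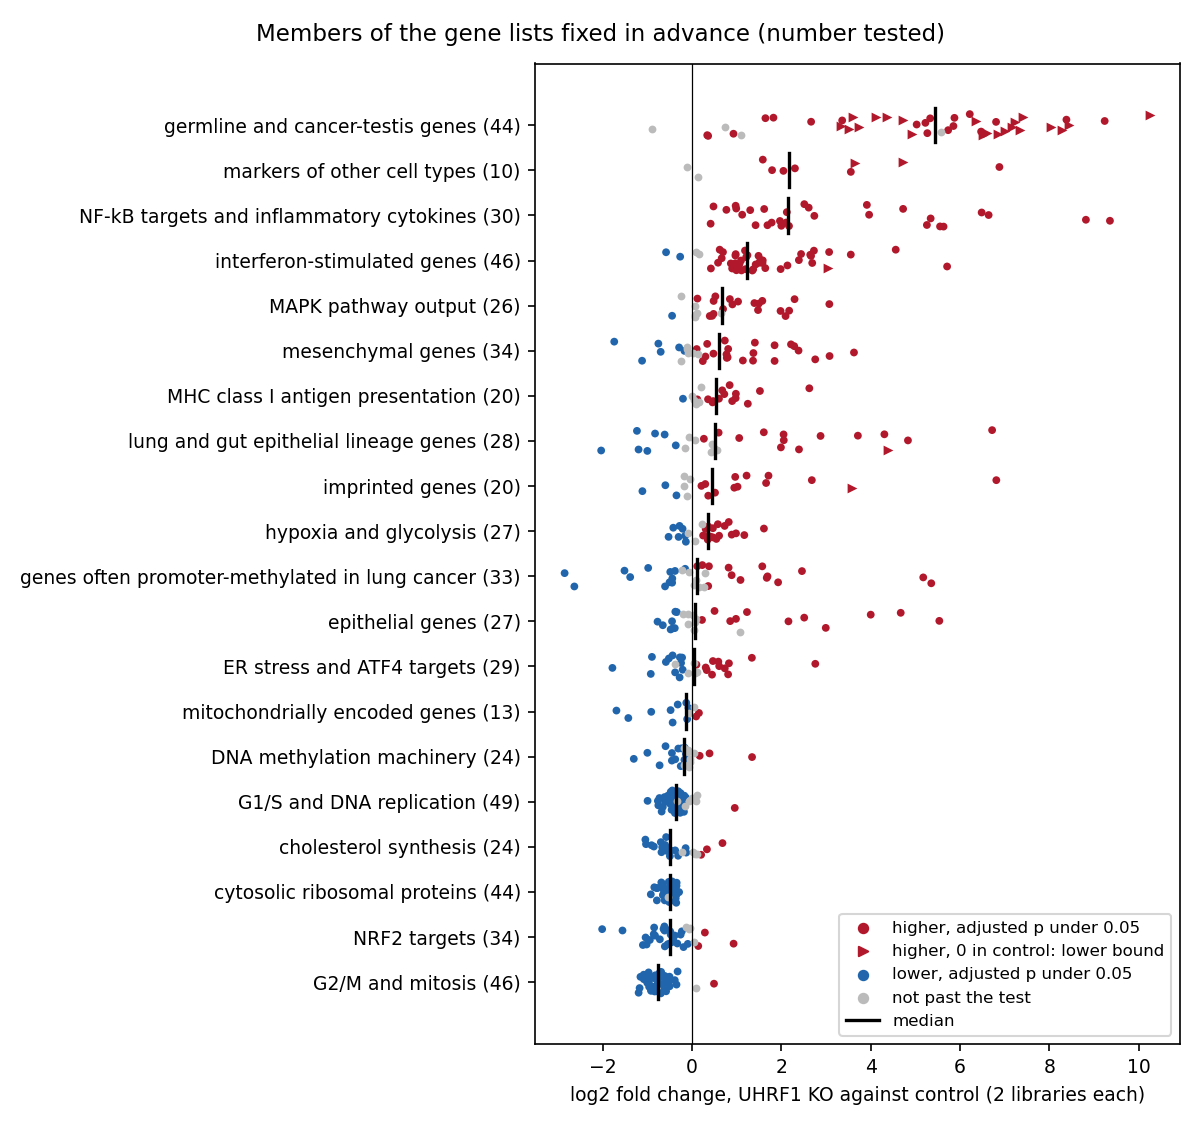
Log2 fold change (horizontal axis, UHRF1 KO against control, 2 libraries each) of every tested member of 20 gene lists, with the number tested beside each list and genes at 0 in control drawn at their lower bound. Black bars mark medians, which run from 5.45 for the germline and cancer-testis genes to -0.76 for G2/M genes; the medians of the epithelial, promoter-methylated and ER stress lists turned negative when libraries were recentred.

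Genes that read, write or maintain DNA methylation were mostly slightly lower. Of 24 tested, 3 rose and 13 fell (3 and 14 adjusted over the list alone), with the targeted UHRF1 among the falls. Without it, a check added after seeing the data, 3 of 23 rose and 12 fell (camera adjusted p = 0.0177, and adjusted p = 0.377 with an estimated correlation). DNMT3B, a de novo methyltransferase, rose from 9.73 ± 0.27 to 24.7 ± 1.04 CPM (log2 fold change 1.34, SE 0.10), while CDCA7L fell by 1.00 and the 5-methylcytosine oxidase TET3 by 0.73 on the log2 scale. DNMT1 was at 160.8 ± 0.94 CPM in control and 145.9 ± 0.50 CPM in UHRF1 KO, a log2 fold change of -0.14 (edgeR adjusted p = 0.0042), and the call was lost without UHRF1 KO replicate 2 (adjusted p = 0.0619, against 1.21e-15 to 0.0421 in the other 13 alternative fits). DNMT3A (log2 fold change -0.09, edgeR adjusted p = 0.296) and UHRF2 (-0.04, edgeR adjusted p = 0.546) did not pass the test. DNMT3A was called lower with libraries recentred (log2 fold change -0.38, edgeR adjusted p = 1.45e-05, against 0.105 to 0.800 in the other 13 alternative fits). The UHRF2 value turned to 0.16 (edgeR adjusted p = 0.0159) when GC content and length trends were removed and was -0.14 (edgeR adjusted p = 0.0350) with recentring, against adjusted p from 0.298 to 0.838 in the other 12. The list had a median of -0.17 and a camera adjusted p of 0.00873, and adjusted p = 0.364 with an estimated correlation, and the median was -0.47 with libraries recentred.

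Germline and cancer-testis genes, which are normally silent outside the germ line, were the most strongly raised of the lists. Of 60 members 44 passed the expression filter and were tested, and of these 40 rose, 37 of them at least 2-fold, and 0 fell (40 and 0 adjusted over the list alone). No member fell at an unadjusted edgeR p under 0.05 or in DESeq2 or limma-voom. In both control libraries 22 of the 44 had 0 counts. These 22 passed the filter through the UHRF1 KO libraries alone and could only rise. The member counts and the list test thus follow in part from the filter. The list test was not repeated among genes with counts in both controls. MAGEA3 rose 38.6-fold, from 1.64 ± 0.42 to 63.8 ± 2.80 CPM, and the germ cell and meiosis genes DAZL and SPATA22 were at least 30.3-fold and at least 26.6-fold higher. PRAME, already at 146.8 CPM in control, rose by a log2 fold change of 0.36. The median log2 fold change was 7.33, or 5.45 with genes at 0 in control set to their bound (camera adjusted p = 3.44e-16, and adjusted p = 0.110 with an estimated correlation). Many MAGE, GAGE, PAGE and SSX genes have near-identical copies, so counts of single members are uncertain.

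Genes known for promoter methylation in lung cancer went both ways. Of 33 tested among 46, 14 rose and 12 fell (14 and 12 adjusted over the list alone). TFPI2, a serine protease inhibitor, rose 5.50-fold from 145.8 ± 1.75 to 802.4 ± 14.6 CPM, and RASSF2 fell 2.62-fold from 44.9 ± 1.84 to 17.1 ± 1.79 CPM. SFRP5 rose 2.97-fold, while CADM1 and DKK3 fell by 1.52 and 0.98 on the log2 scale. The median was 0.11 (camera adjusted p = 0.820), 0.04 without control replicate 2 and -0.22 with libraries recentred.

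Of 20 imprinted genes tested among 29, 13 rose and 3 fell (13 and 4 adjusted over the list alone). The long noncoding RNAs MEG3 and H19 rose 6.42-fold, to 141.9 ± 2.21 CPM, and 112.6-fold, from 0.22 ± 0.072 to 25.4 ± 0.37 CPM. PEG10 and SGCE, neighbours on chromosome 7, fell by 1.11 and 0.60 on the log2 scale. The list median of 0.44 did not pass camera (adjusted p = 0.109) and was 0.17 with libraries recentred.

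Interferon-stimulated genes rose together. Of 46 tested, 42 rose and 2 fell (43 and 2 adjusted over the list alone), with a median of 1.22. The ubiquitin-like ISG15 rose 5.43-fold, from 63.9 ± 2.41 to 347.0 ± 1.80 CPM (3.44-fold with libraries recentred), and LGALS3BP rose 2.68-fold to 534.5 ± 23.99 CPM. The interferon genes IFNL1 and IFNB1, also on the list, rose by log2 fold changes of 2.69 and 1.18. EIF2AK2 and IFIT5 were the 2 that fell, by 0.58 and 0.27 on the log2 scale. The camera adjusted p was 4.60e-12, and adjusted p = 0.110 with an estimated correlation.

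Genes of MHC class I antigen presentation rose in 14 of 20 cases and fell in 1 (14 and 1 adjusted over the list alone). HLA-C rose 2.37-fold from 57.2 ± 4.91 to 135.7 ± 2.20 CPM and HLA-B rose 6.17-fold from 4.42 ± 0.070 to 27.3 ± 0.85 CPM. B2M, the shared light chain, rose by 0.67 and the loading factor TAPBP by 0.98, and the chaperone CANX fell by 0.21 on the log2 scale. HLA genes are similar in sequence and HLA-B and HLA-C overlap in the annotation used, so their single counts are uncertain. The median was 0.54, or 0.24 with libraries recentred (camera adjusted p = 6.03e-04, and adjusted p = 0.159 with an estimated correlation). CD274, which encodes PD-L1, rose from 1.57 ± 0.0050 to 3.78 ± 0.86 CPM, a log2 fold change of 1.26 (SE 0.26, edgeR adjusted p = 9.12e-05), on 28 and 29 counts against 91 and 79.

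All 30 tested NF-kB targets and inflammatory cytokines rose (30 and 0 adjusted over the list alone), 25 of them at least 2-fold. DESeq2 called 29 of them higher, limma-voom 30, and 0 fell with either tool or at an unadjusted edgeR p under 0.05. TNFAIP3, a feedback inhibitor of NF-kB, rose 15.6-fold from 25.3 ± 0.010 to 395.8 ± 3.10 CPM (chromosome 6, 137867188 to 137883312). Mitochondrial superoxide dismutase SOD2 rose 6.11-fold to 1219 ± 14.2 CPM. The cytokine genes IL6 and CCL20 rose by log2 fold changes of 3.91 and 5.34, and CSF3 went from 7 counts over both controls to 5948 over both UHRF1 KO libraries. The median was 2.15 (camera adjusted p = 1.92e-14, and adjusted p = 0.110 with an estimated correlation).

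Cell cycle genes fell. Of 46 G2/M genes, 44 fell and 1 rose (44 and 1 adjusted over the list alone), with a median of -0.76. TOP2A, the topoisomerase of dividing cells, fell 2.04-fold from 771.5 ± 41.6 to 377.9 ± 9.92 CPM, and cyclin B1 (CCNB1) fell 2.23-fold from 246.3 ± 12.2 to 110.4 ± 0.77 CPM. CDC25B was the 1 that rose, by a log2 fold change of 0.49. Of 49 G1/S and replication genes, 41 fell and 1 rose (43 and 1 adjusted over the list alone), with a median of -0.36, or -0.64 with libraries recentred. Symbol families such as MRPL had a median as low (-0.46), so a fall of this size was not particular to G1/S genes. RRM1 and MCM7 fell 1.66-fold and 1.54-fold, and cyclin E1 (CCNE1) was the 1 that rose, by a log2 fold change of 0.96. The camera adjusted p was 1.92e-14 for G2/M and 1.07e-08 for G1/S, and adjusted p = 0.110 and 0.159 with an estimated correlation.

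**Figure D2:**
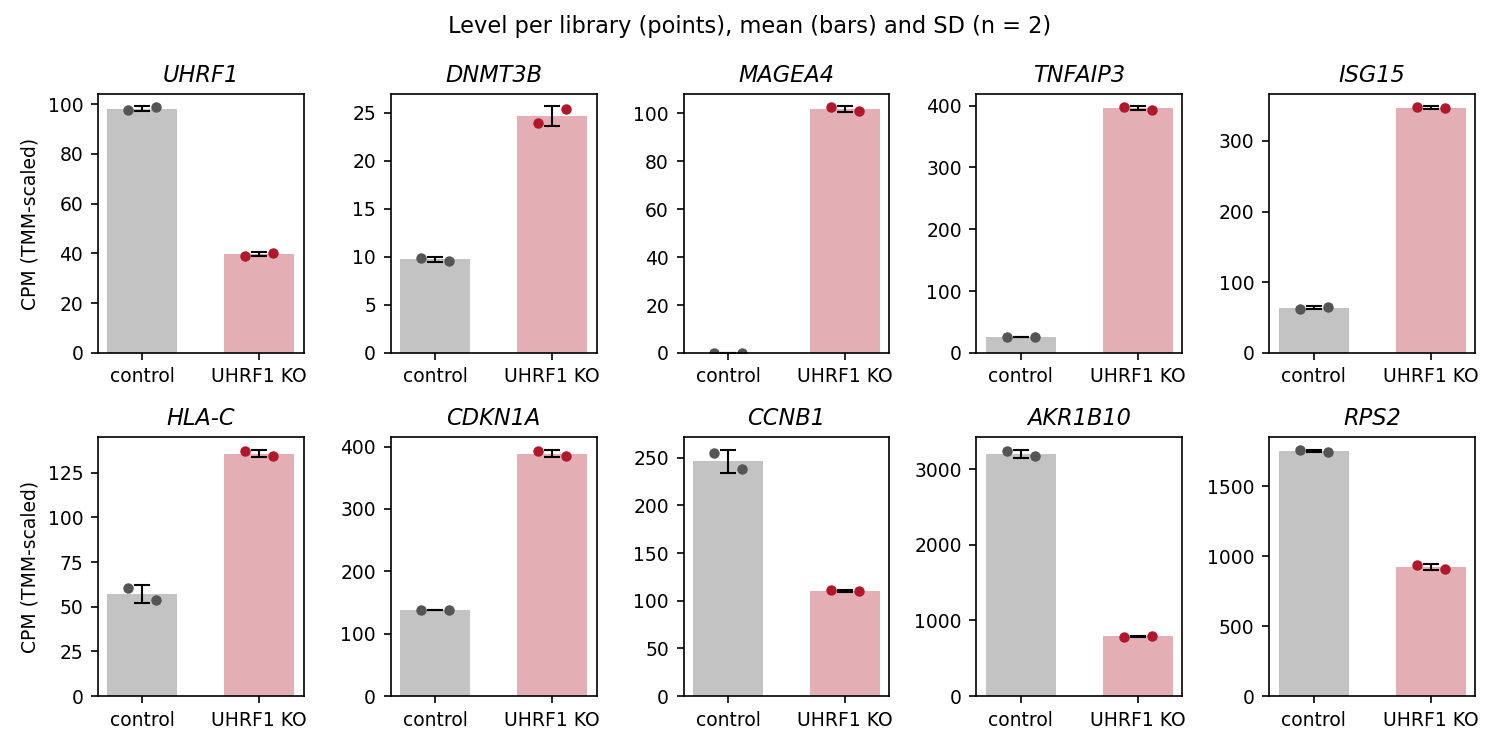
CPM after TMM scaling (vertical axis, from 0) of 10 named genes in control and UHRF1 KO, with each library as a point, the mean as a bar and the SD (n = 2) as a line. In each gene both UHRF1 KO libraries lie on one side of both control libraries, with UHRF1 at 98.2 CPM in control and 39.7 CPM in UHRF1 KO.

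CDKN1A, the p21 cell cycle inhibitor, rose 2.82-fold from 138.1 ± 0.33 to 388.9 ± 6.28 CPM. CDKN2A and CDKN2B, which A549 cells are known to lack, had 0 counts in all 4 libraries, where 3 counts in the smallest library would be 0.161 CPM.

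Targets of NRF2, a regulator that is constitutively active in A549, were mostly lower. Of 34, 27 fell and 3 rose (27 and 3 adjusted over the list alone). The aldo-keto reductase AKR1B10 fell 4.04-fold from 3204 ± 53.5 to 792.4 ± 8.13 CPM, and AKR1C3 fell 2.15-fold from 1811 ± 17.8 to 842.9 ± 0.95 CPM. NQO1 fell by 0.59 on the log2 scale, and ALDH3A1, ABCC3 and NMRAL2P rose by log2 fold changes of 0.29, 0.14 and 0.93. The AKR1C genes are close copies, so their split is uncertain. The median was -0.50, or -0.85 with libraries recentred (camera adjusted p = 1.85e-07, and adjusted p = 0.159 with an estimated correlation). Cytosolic ribosomal protein genes also had a median of -0.50, so a median of this size was not particular to NRF2 targets.

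Output genes of the MAPK pathway rose in 19 of 26 cases and fell in 1 (20 and 1 adjusted over the list alone). The immediate-early gene EGR1 rose 4.91-fold from 131.6 ± 1.47 to 645.9 ± 7.62 CPM, and IER3 rose 4.51-fold to 571.3 ± 4.87 CPM (2.88-fold with libraries recentred). FOSL1 and the phosphatase DUSP6 rose by log2 fold changes of 1.49 and 1.48, and SPRY2 was the 1 that fell, by 0.45. The median was 0.67 (camera adjusted p = 7.60e-06, and adjusted p = 0.159 with an estimated correlation).

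Mesenchymal genes rose in 22 of 34 cases and fell in 6 (22 and 6 adjusted over the list alone). The collagen gene COL6A1 rose 6.76-fold from 37.4 ± 2.95 to 252.8 ± 0.078 CPM. SNAI1 rose by a log2 fold change of 2.29, while FN1 and THBS1 fell by 0.70 and 1.75. The median was 0.61, or 0.26 with libraries recentred (camera adjusted p = 0.00492, and adjusted p = 0.334 with an estimated correlation). Markers of other cell types moved in the same direction. Of 10 that could be tested out of 27, 8 rose and 0 fell (8 and 0 adjusted over the list alone, and 8 and 0 with DESeq2, with limma-voom and at an unadjusted edgeR p under 0.05). Of the 10, 2 had 0 counts in both controls and passed the filter through the UHRF1 KO libraries alone, so they could only rise. PECAM1, an endothelial adhesion molecule, rose 118.1-fold from 0.25 ± 0.20 to 29.9 ± 0.89 CPM on 7 and 2 control counts (260.1-fold without control replicate 1 and 74.0-fold without control replicate 2), and the collagen gene COL1A1 rose 4.13-fold from 3.78 ± 0.83 to 15.6 ± 1.17 CPM. Their median was 2.17 (camera adjusted p = 0.00196, and adjusted p = 0.159 with an estimated correlation).

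Epithelial genes went both ways, with 11 of 27 tested among 33 higher and 8 lower (12 and 9 adjusted over the list alone). CLDN4 rose 7.97-fold from 6.32 ± 0.29 to 50.4 ± 1.32 CPM and ELF3 rose 2.34-fold to 193.1 ± 0.54 CPM, while CDH1 and KRT18 fell by 0.39 and 0.43 on the log2 scale. The median was 0.06 (camera adjusted p = 0.393), from 0.03 with no filter to 0.17 with GC content and length trends removed, 0.12 without control replicate 2 and -0.13 with libraries recentred. Of 28 lung and gut lineage genes tested among 41, 14 rose and 7 fell (14 and 7 adjusted over the list alone). The mucin genes MUC5B and MUC13 rose 4.15-fold, to 280.5 ± 4.80 CPM, and 4.14-fold, to 123.6 ± 3.38 CPM, and the transcription factor gene SOX2 fell by 2.04 on the log2 scale. The list median of 0.52, or 0.27 with libraries recentred, did not pass camera (adjusted p = 0.0921), and the list passed without control replicate 2 (adjusted p = 0.0211).

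Cholesterol synthesis genes fell in 17 of 24 cases and rose in 3 (18 and 3 adjusted over the list alone). HMGCS1 fell 2.05-fold from 364.1 ± 0.055 to 178.0 ± 7.40 CPM and FDPS fell 1.88-fold to 85.2 ± 2.82 CPM, while STARD4, which carries cholesterol, rose by a log2 fold change of 0.20. The median was -0.49, or -0.73 with libraries recentred (camera adjusted p = 5.58e-04, and adjusted p = 0.159 with an estimated correlation). The symbol family MRPL had a median near this (-0.46), so a median of this size was not particular to cholesterol synthesis genes. Of 29 ER stress and ATF4 targets, 12 rose and 12 fell (12 and 12 adjusted over the list alone). ATF3 rose 6.77-fold to 132.6 ± 3.30 CPM, and PSAT1, of serine synthesis, fell 1.87-fold to 141.3 ± 0.27 CPM. The median was 0.04 and the mean 0.08, while the direction in camera was down (adjusted p = 0.747). The median was 0.01 without control replicate 1, -0.03 without control replicate 2, -0.14 without UHRF1 KO replicate 2, -0.03 with GC content and length trends removed and -0.33 with libraries recentred. Hypoxia and glycolysis genes rose in 17 of 27 cases and fell in 7 (17 and 7 adjusted over the list alone). BHLHE40 rose 3.05-fold to 822.2 ± 4.03 CPM and VEGFA rose 1.85-fold to 110.2 ± 3.01 CPM, while ENO1 and GAPDH fell by 0.53 and 0.42 on the log2 scale. The median was 0.35, or 0.06 with libraries recentred (camera adjusted p = 0.0568), and the list passed with a minimum of 1 CPM (adjusted p = 0.0399) and without UHRF1 KO replicate 2 (adjusted p = 0.0449).

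Cytosolic ribosomal protein genes fell in 43 of 44 cases (44 adjusted over the list alone), and 0 rose, with 0 higher also in DESeq2, in limma-voom and at an unadjusted edgeR p under 0.05. RPS2 fell 1.90-fold from 1751 ± 8.76 to 922.2 ± 21.2 CPM and RPL7 fell 1.73-fold to 564.2 ± 1.30 CPM. The median was -0.50, or -0.85 with libraries recentred (camera adjusted p = 1.96e-13, and adjusted p = 0.364 with an estimated correlation). Of 13 mitochondrially encoded protein genes, 9 fell and 2 rose (9 and 2 adjusted over the list alone). MT-ND6 fell 3.24-fold to 212.1 ± 11.1 CPM and MT-ND5 fell 2.69-fold to 1200 ± 41.2 CPM, while MT-ND2 and MT-ND4 rose by log2 fold changes of 0.15 and 0.09. The median was -0.13, or -0.22 without UHRF1 KO replicate 1 and -0.49 with libraries recentred (camera adjusted p = 0.0116, and adjusted p = 0.409 with an estimated correlation). MT-ND5 and MT-ND6 end next to each other on opposite strands, and strand use in counting is not given in the sources used here. Mitochondrial ribosomal RNA took 2.10% and 2.02% of the counts in the control libraries and 1.37% and 1.40% in the UHRF1 KO libraries, and the 10 most abundant genes took 9.84% and 9.48% against 8.05% and 8.05%. The ribosomal, mitochondrial and other cell type lists were meant as checks of sample makeup and RNA, and each was called by camera with its preset correlation. A difference in RNA makeup between the groups was not tested as a cause of moderate falls.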

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

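Thinning to equal depth, both removals of GC content and length trends, and the 2-fold counts as results of their own were chosen after seeing the data. UHRF1 kept its direction and call under all 14 alternative fits, with log2 fold changes from -1.28 (upper-quartile factors) to -1.68 (trends removed, libraries recentred). Of the 57 named genes, 53 kept direction and call in all 14 alternative fits. The exceptions were RN7SL2, DNMT1 (adjusted p = 0.0619 without UHRF1 KO replicate 2), DNMT3A (called lower with recentring) and UHRF2, whose log2 fold change reversed to 0.16 with trends removed and was -0.14 with recentring; the cause was not tested. RN7SL2 lost its call in 4 settings, with adjusted p from 0.0689 to 0.212.

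The counts of 5445 higher and 5118 lower genes became 3543 and 8220 with trends removed and libraries recentred on their means, where 1259 genes were at least 2-fold lower. That setting moves the centre of every library by construction, so the count follows the chosen centre. With a minimum of 2-fold the counts were 2616 and 432 by construction. An adjusted p under 0.01 left 4617 and 4309. DESeq2 called 3845 higher and 3828 lower genes, limma-voom 5368 and 5050, RLE factors 5450 and 5162, upper-quartile factors 5696 and 4822, no filter 5781 and 5382, and a minimum of 1 CPM 5045 and 4782. Leaving out 1 library gave 4626 to 5137 higher and 4388 to 5037 lower genes, and 2393 to 2744 at least 2-fold higher and 421 to 461 lower; the lone library is then assumed to vary like the other group.

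The replicate numbers do not pair the libraries: deviations of same-numbered libraries from their group means correlated at -0.014 across genes. With the number as a block, 5280 genes were higher and 4986 lower, and among named genes and lists it changed the call of RN7SL2 (adjusted p = 0.139) and no other.

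Of the lists, 7 were called higher and 7 lower with TMM, RLE and upper-quartile factors, with no filter, with the block and after thinning, and 7 or 8 higher and 7 lower with a minimum of 1 CPM or 1 library left out; the list tests were not run with GC content and length trends removed. With an estimated correlation camera called 0 higher and 0 lower (4 and 1 at an unadjusted p under 0.05), on 2 residual degrees of freedom, and fry called 13 higher and 7 lower. In the simulation 17 of 49 genes at 1.2-fold were called, against 42 of 50 at 2-fold. Far fewer genes were changed there than were called in the real data, which made its adjusted threshold stricter. The share of small changes missed in the real comparison is therefore not known.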

Other observations

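The tests of gene families, gene types, chromosomes, GC content and length, genes silent in control and other cell types, and the thinning to equal depth, were chosen after the result was seen; only the bounds for thinning and for the X chromosome without cancer-testis genes were set before their results. Genes named as examples in this part were chosen after their values were seen. The Fisher tests of families, gene types and chromosomes treat genes as independent, so genes that move together make their p-values too small. No test that allows for such correlation was run on these groups.

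Families that share a symbol prefix were tested for genes at least 2-fold higher (240 families, one-sided Fisher test, Benjamini-Hochberg adjusted), and 19 passed. The expression filter admits genes that rise from low levels, and among genes with 10 or more counts in both controls 6 passed, all among the 19. Genes with the prefix IL, mostly interleukins and their receptors but also IL4I1 and IL18BP, rose at least 2-fold in 24 of 45 cases (adjusted p = 4.20e-08; 10 of 30 and adjusted p = 0.00247 with counts in both controls) and the mucins in 10 of 12 (adjusted p = 5.08e-06; 4 of 5 and adjusted p = 0.00665). The collagen prefix rose at least 2-fold in 18 of 32 and fell at least 2-fold in 3 (adjusted p = 1.28e-06; 9 of 23 higher and adjusted p = 0.00211 with counts in both controls), although it also takes in COL4A3BP, which is no collagen. COL6A3 rose from 0.17 ± 0.082 to 79.7 ± 2.28 CPM and COL7A1 3.19-fold from 175.7 ± 4.42 CPM, while COL12A1 fell by 1.40 on the log2 scale. The mucin MUC16 had a count ratio of 396.8 (95% counting interval 135.5 to 1926) between UHRF1 KO and control. Keratins went both ways, with 9 of 20 at least 2-fold higher (one-sided Fisher adjusted p = 0.0115, and 2 of 13, not passing, with counts in both controls). The 2 at least 2-fold lower were KRT10 and KRT222, by 1.27 and 1.76 on the log2 scale. KRT17 rose from 0.41 ± 0.18 to 56.7 ± 0.76 CPM, while the abundant KRT8 fell by only 0.34 on the log2 scale. The prefix MMP, matrix metalloproteinases and the opposite-strand gene MMP24OS, rose at least 2-fold in 9 of 14 cases (adjusted p = 5.34e-04; 3 of 8 and adjusted p = 0.279 with counts in both controls), among them MMP2 at 8.45-fold. The prefix PDE, phosphodiesterases and their interactor PDE4DIP, was the 1 family that passed for falls, with 5 of 22 at least 2-fold lower (adjusted p = 0.0205; 5 of 19 and adjusted p = 0.0145 with counts in both controls) and 5 at least 2-fold higher, and PDE1C fell by 1.52. Medians of the families named kept their sign in all 14 alternative fits except PDE, whose median of -0.10 was 0.05 with GC content and length trends removed.

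Among long noncoding RNA genes, 254 of 779 lincRNA genes (32.6%) and 252 of 939 antisense genes (26.8%) were at least 2-fold higher, against 13.3% of protein-coding genes (odds ratios 3.16 and 2.40, two-sided Fisher p = 8.63e-41 and 4.97e-26). Among genes with 10 or more counts in both controls the shares were 12.8% and 13.4% against 7.27% (odds ratios 1.87 and 1.98, two-sided Fisher exact p = 3.81e-05 and 2.01e-07). The lincRNA share of counts was 0.333% and 0.337% in control and 0.605% and 0.611% in UHRF1 KO. Antisense genes cannot be told from their sense partners where counting did not use strand. Histone genes (prefix HIST) rose at least 2-fold in 12 of 27 cases (one-sided Fisher adjusted p = 0.00193), among them HIST1H1C at 3.62-fold. With 10 or more counts in both controls it was 8 of 23 (one-sided Fisher adjusted p = 0.00665). Histone genes have near-identical copies, and how fully the mRNA kit captured their transcripts is not given in the sources used here. On chromosome 5, 27 of 610 coding genes were at least 2-fold lower (two-sided Fisher adjusted p = 0.0103 over 23 chromosomes; 27 of 568 and 0.0115 with 10 or more counts in both controls), and on chromosome 19, 158 of 966 were at least 2-fold higher (adjusted p = 0.0493; 92 of 878 and 0.00768).

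The larger changes were mostly rises, 2616 against 432 at least 2-fold, a ratio of 6.06. Greater depth of the UHRF1 KO libraries is argued against by thinning to equal totals, which left a ratio of 6.03. Removing GC content and length trends without recentring left 4.95. That version was run after the recentred one, with bounds set after the result, so it does not decide on these trends as a cause. Removal with recentring gave 1.56, so the ratio itself depends on which level is taken as unchanged, and RNA content per cell was not measured here; with genes at 0 in both controls at their lower bound, 797 genes were at least 8-fold higher and 13 lower, and 673 and 20 with recentring. With 0 counts in both controls 339 genes had 10 or more in both UHRF1 KO libraries, and 0 genes did the reverse, a count that follows in part from the excess itself and does not single out a cause. Loss of silencing, on which DNA methylation was not analysed here, and clonal difference between the cell populations both stay open. Any other effect of the guide is confounded with the group as well, since the labels name no second UHRF1 guide and no rescue.

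Markers of other cell types rose (8 of 10 tested), and 1 of the 27 on that list is also on the mesenchymal list. Admixed endothelial cells would bring their other abundant transcripts, but VWF, CDH5 and KDR together had 2.27% of the 1366 counts of PECAM1 in UHRF1 KO. For fibroblasts COL3A1 and DCN had 4.17% of the counts of COL1A1 and COL1A2, and for monocytes or macrophages LYZ and CD68 had 2.86% of the counts of CD14, so these cells are unlikely as the source of the rises. Expression of single lineage genes within A549 cells remains a hypothesis and was not tested further.

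On the X chromosome 114 of 519 coding genes were at least 2-fold higher, against 12.9% elsewhere (odds ratio 1.90, 95% interval 1.52 to 2.35, two-sided Fisher adjusted p = 7.47e-07). Among genes with 10 or more counts in both controls, 26 of 417 X genes (6.24%) against 7.31% elsewhere were higher (odds ratio 0.844, 0.541 to 1.26), so the excess was seen only where genes with few or no control counts were included. Cancer-testis genes could account for it. Without 40 such genes, 17.1% of X genes against 12.8% elsewhere were higher, with an odds ratio of 1.40 (1.09 to 1.79, two-sided Fisher p = 0.00841). The interval lies above 1, which argues against these 40 genes as the whole of the excess. It also holds a ratio of 1.2, the bound set for that explanation. By that bound, cancer-testis genes alone cannot be told apart from a wider set of X genes with low control counts. Whether other cancer-testis genes were among the remaining X genes was not checked.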
